A study of Mus musculus and Danio rerio with 18 samples.

How the data were processed

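RNA sequencing of mouse thymocytes and zebrafish embryos lacking Tnpo3, a nuclear import receptor for serine/arginine-rich (SR) splicing factors, was compared with matching controls. The mouse comparison used mature CD4 single-positive (CD4SP) thymocytes sorted as CD4 positive, CD8 negative, TCR beta high and CD24 low, 3 libraries from animals homozygous for a floxed Tnpo3 allele with Lck-driven Cre and 3 from heterozygous controls. The zebrafish comparison used whole embryos at 4 days after fertilization, 3 mutant and 3 wild-type libraries. The series lists 18 samples in 6 groups; the 6 libraries of double-positive thymocytes were not analysed here. Libraries were made from total RNA with a stranded kit after depletion of ribosomal RNA, per the labels' protocols. The labels do not say that the replicates came from separate animals or clutches. P-values for single genes or exons therefore cover no more than the spread between these libraries, which may be technical. Tests of direction, lists, overlaps, levels, lengths, neighbours and motifs took genes or exons as units. These units share the same libraries and are not independent, and such p-values do not include the spread between libraries. In the quasi-binomial model below, that spread was largely pooled over events and was not the spread of each exon.

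Reads were processed with TopHat2 2.0.13, Bowtie2 2.2.3 and featureCounts 1.4.5-p1 on the GRCm38 mouse and Zv9 zebrafish builds, per the submitters' processing notes. Differential expression came from edgeR 3.12.0 for mouse and DESeq2 1.6.3 for zebrafish, per the submitters' processing notes and the file headers. Both tables hold log2 fold changes fitted by the authors and their raw and adjusted p-values. The deposited F and Wald statistics of those tests are scores and were not used beyond reading them. The zebrafish values also include the standard error of each log2 fold change and a mean signal, the normalised count averaged over libraries by the authors; the mouse values include the authors' mean log2 CPM. Both expression tables list changed genes only, 240 mouse genes with a highest adjusted p of 0.00995 and 740 zebrafish genes with a highest adjusted p of 0.0494. The ratio of adjusted to raw p put 14650 mouse and 22995 zebrafish genes behind the adjustment. Zebrafish genes carried identifiers without symbols, and 418 of the 740 were given the symbol paired with the same identifier in the splicing table.

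Exon skipping came from rMATS tables of junction reads, and the rMATS version was not given in the sources used here. Each deposited event gave inclusion and skipping junction reads for 3 libraries in each of 2 groups, the inclusion level per library, the difference in mean inclusion level as a score from -1 to 1 and the authors' p-value and adjusted p (FDR). The inclusion level estimates the share of molecules that keep the exon. Reads are first divided by the deposited form lengths of each event, at most 120 bases for inclusion and 60 for skipping. Where the skipping length is short, a few skipping reads lower the level strongly. Recomputed levels differed from the deposited ones by at most 0.0005. The junction reads were treated as read numbers per form within an event, not as gene counts, so edgeR and DESeq2 were not rerun. The files name the rMATS groups only as 1 and 2, and no source used here says which holds the mutant libraries; differences in inclusion are therefore given as group 2 against group 1, with no genotype. The expression tables likewise do not name the group in the numerator of the fold. The 2 kinds of table were tied through junction reads summed per gene: the sign of the fold was that of group 2 minus group 1 for 115 of 116 mouse genes (99.1%) and 417 of 423 zebrafish genes (98.6%). A negative fold thus denotes lower expression in group 2.

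An event was tested when it had a mean of at least 10 junction reads per library, at least 3 in every library and at least 5 reads of the rarer form over all libraries. This kept 25869 of 53548 mouse events (48.31%) in 7256 genes and 11112 of 28035 zebrafish events (39.64%) in 6624 genes. A changed event had an rMATS FDR below 0.05 and a difference in inclusion of at least 0.1. Beside the rMATS test, a quasi-binomial logistic model of inclusion against skipping reads was fitted per event in R 4.3.3, with the spread between libraries moderated over events by limma 3.58.1 and Benjamini-Hochberg adjustment. The moderated spread followed a trend in read depth and was never set below binomial. Its median was 2.71 times binomial in mouse and 3.40 times in zebrafish. The median prior degrees of freedom were infinite in both species, so the spread of a typical event's own libraries had no weight. Small p-values of this model can therefore go with widely varying libraries. Groups with fewer than 5 reads of the rarer form gave no degrees of freedom to the moderated spread, a choice made after seeing the data. Where a sentence gives an adjusted p for an exon with inclusion values per group, it comes from this model. On data simulated from the real read depths, with 200 changed events per species, the model recovered 19% of mouse events changed by 1 on the log2 odds scale and 76% of those changed by 2, among 25869 events, with 5% false calls; in zebrafish, among 11112 events, it recovered 20% and 70% with 4.26% false calls. Limma on logit inclusion recovered 0% and 2% in mouse and 1% and 42% in zebrafish, at the same changes. In the simulation, changed events were drawn away from full inclusion and full skipping, and all events had the same spread setting. Calls there used the adjusted p without a minimum difference. These rates therefore do not carry over to the real calls, many of which were near full inclusion.

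Direction was tested with an exact binomial test on 1 event per gene, the one with the largest difference. Gene lists and overlaps were tested with two-sided Fisher's exact tests among genes that had a tested event, and lists in the expression tables by the split of positive against negative folds, each with Benjamini-Hochberg adjustment over the lists of a species. Gene lists covered splicing factors, nuclear transport, cell cycle, p53 targets, stress, ribosome biogenesis, interferon response and markers of the cell types each sample could hold. Exon and intron lengths were compared by two-sided permutation tests with 100000 resamples (10000 for alternatives), and shares of exons divisible by 3 by Fisher's exact test, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6; figures used matplotlib 3.10.9. Mouse exons were placed in GENCODE vM21 gene models on GRCm38, and exon numbers refer to the principal transcript. No zebrafish annotation of the build was used here. Genes were matched between species by identical symbol, ignoring case. Intervals are exact 95% binomial intervals, 95% intervals of odds ratios or, for motif densities, bootstrap percentiles over exons; they cover sampling of genes or exons, not of animals.

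The tests, the gene lists, the thresholds and the rule for naming genes were fixed before the data were examined, except where stated. The rule named the targeted gene; the 10 genes with the largest positive and the 10 with the largest negative fold among listed genes with a proper symbol; the 10 events with the largest difference each way, 1 per gene; up to 4 members per list by lowest adjusted p; genes changed in both species; and up to 10 genes changed in both expression and splicing by lowest splicing FDR. Alternatives covered the read minimum, no read filter, differences of 0.05 and 0.2, an FDR of 0.01, the quasi-binomial model, limma on logit inclusion with pseudocounts of 0.5 and 2 reads, each library left out, an adjusted p of 0.01 or a log2 fold change of at least 1 for expression, expression without the listed genes of lowest level, logistic models with reads and events as covariates, and matched unchanged exons.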

Results

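The data compare RNA of Tnpo3 mutants and controls, in mature CD4SP thymocytes of the mouse and in whole zebrafish embryos at 4 days. Each species had 3 libraries per group. Junction reads summed over all exon-skipping events ran from 23647517 to 28318061 per mouse library and from 15711487 to 18650509 per zebrafish library. A read was counted in every event that uses its junction, so these totals and the shares of skipping reads below count some reads more than once. Tested events had a median of 238 junction reads per library in mouse and 185 in zebrafish. Skipping reads made up 3.04% to 3.10% of junction reads in mouse group 1 and 3.34% to 3.49% in group 2. In zebrafish the shares were 2.54% to 2.61% in group 1 and 2.81% to 2.88% in group 2, without overlap between groups in either species.

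The targeted gene differed between the groups in both species. In mouse, Tnpo3 (ENSMUSG00000012535.10) lost a 139 bp coding exon, exon 7, at chromosome 6, 29578463 to 29578601 on the minus strand: its inclusion level was 0.653 ± 0.035 (SD, n = 3) in group 1 and 0.0196 ± 0.034 (SD, n = 3) in group 2. The group 1 libraries stood at 0.629, 0.693 and 0.635, and the group 2 libraries at 0.0588, 0 and 0. Over the 3 libraries, 750 inclusion and 200 skipping reads of Tnpo3 exon 7 in group 1 faced 16 and 393 in group 2 (quasi-binomial adjusted p = 1.18e-57). The mouse allele is floxed, and junction reads cannot tell an exon deleted from the DNA by Cre from one skipped in splicing. The Tnpo3 event is therefore no evidence of changed splicing. In the authors' deposited table Tnpo3 RNA had a log2 fold change of -0.45 with an adjusted p of 0.00913. Zebrafish tnpo3 (ENSDARG00000045680) fell by 1.41 on the log2 scale in the authors' deposited table, with a standard error of 0.09 and an adjusted p of 5.94e-47. Its only listed skipping event, a 93 bp exon at chromosome 4, 12666625 to 12666717, had 1377 inclusion reads in group 1 and 364 in group 2 and almost no skipping.

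**Figure D1:**
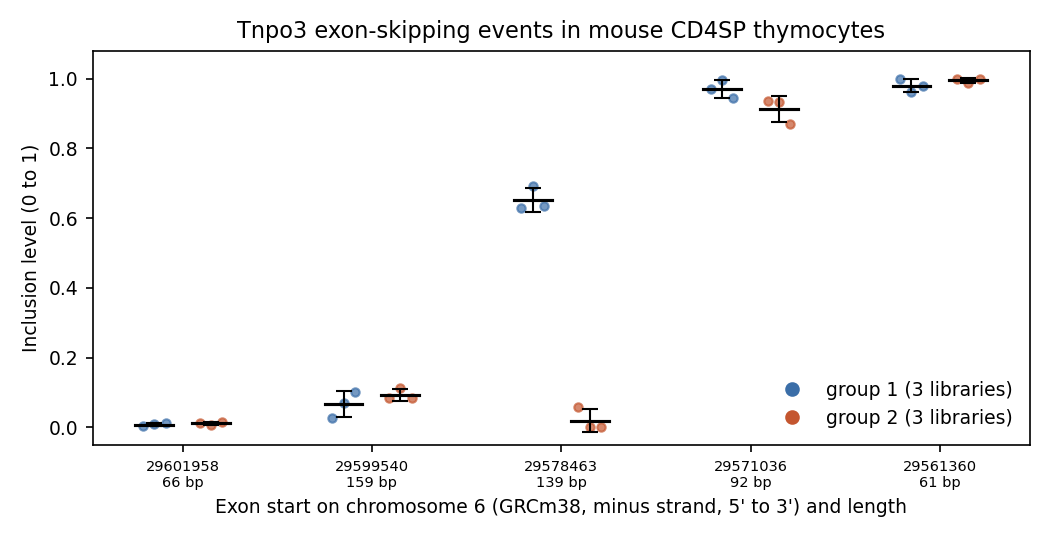
Inclusion level (0 to 1) of the Tnpo3 exons with a tested skipping event in mouse CD4SP thymocytes, in transcript order along chromosome 6. Points are single libraries, bars the mean ± SD of 3 libraries per rMATS group; the 139 bp exon stands at 0.653 in group 1 and 0.0196 in group 2.

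The first comparison asked which genes changed their RNA level in CD4SP thymocytes. The authors' deposited table listed 240 genes, 142 with a positive fold and 98 with a negative fold, the sign that Tnpo3 itself had. In the authors' deposited table, the positive folds were large and sat on weakly expressed genes: their median log2 fold change was 2.2 at a median level of 0.74 log2 CPM, against -0.81 at 4.41 log2 CPM for the negative folds. The medians of the level differed by -3.67 log2 CPM (permutation test, p = 2e-05, the smallest it could give). Below 1 log2 CPM stood 75 genes with a positive fold and 3 with a negative fold. By the authors' deposited table, 125 positive and 30 negative genes changed by at least 1 on the log2 scale.

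Among genes with a proper symbol, the largest positive folds in the authors' deposited table were those of Stmn4, a neuronal microtubule regulator (5.73), Myrfl (5.70), the transporter gene Abcc12 (5.47), the photoreceptor gene Tulp1 (5.02) and the epithelial transcription factor gene Spdef (4.81). They were followed in the authors' deposited table by the matrix gene Ltbp2 (4.76), the retinal transporter gene Abca4 (4.66), Efhd1 (4.55), the Schlafen gene Slfn4 (4.40) and the ephrin receptor gene Epha8 (4.31). Slfn4 and Myrfl had mean levels of 4.54 and 3.03 log2 CPM in the authors' deposited table, while Stmn4, Tulp1, Abca4, Efhd1 and Epha8 lay below -1 log2 CPM. Among genes with a proper symbol, the largest negative folds in the authors' deposited table were those of Tmie, a hair cell channel component (-2.16), the fucosyltransferase gene Sec1 (-2.14), Lrrc23 (-1.69), and the lactate dehydrogenase gene Ldhd (-1.68). Next among such genes in the authors' deposited table came the collagen gene Col11a2 (-1.56), the growth factor gene Pdgfb (-1.56), Cnga1 (-1.48), the elongation factor gene Tcea2 (-1.40), the mannosidase gene Man1c1 (-1.40) and the galactose mutarotase gene Galm (-1.37).

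None of the 45 genes of T-cell identity and TCR signalling was in the authors' deposited table. The same held for the lists of double-positive thymocytes, cell cycle, core spliceosome, hnRNPs, nuclear transport, p53 targets, ribosome biogenesis, stress, gamma-delta T and NK cells, myeloid cells or thymic stroma. Of the maturation and egress genes, the GTPase genes Gimap5 (0.59) and Gimap3 (-0.65) and the surface antigen gene Ly6c1 (-1.03) had log2 fold changes of both signs in the authors' deposited table. Single members of other lists were Srrm1, an SR-related splicing coactivator (0.56), and the B-cell adaptor gene Blnk (1.59), by log2 fold change in the authors' deposited table. Others there were perforin, Prf1 (-1.20), the interferon-induced gene Ifi27 (-0.91) and the erythroid factor gene Gata1 (-0.94), by log2 fold change in the authors' deposited table. Of the 6 lists with a member, 5 had only 1, too few for a test of signs. A gene missing from a table of changed genes was not shown to be unchanged.

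**Figure D2:**
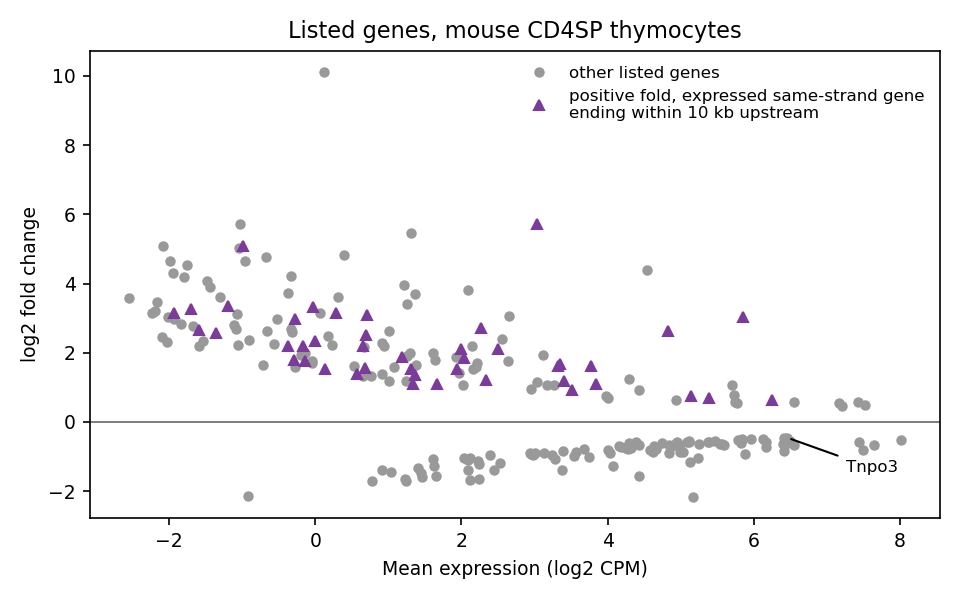
log2 fold change against mean expression (log2 CPM) of the 240 genes in the authors' deposited table for mouse CD4SP thymocytes. Points above 0 are spread over low levels, with 75 of them below 1 log2 CPM, and points below 0 start higher; triangles mark 43 genes with a positive fold that lie downstream of an expressed gene.

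The same comparison in zebrafish embryos gave more genes. The authors' deposited table listed 740 genes, 289 with a positive fold and 451 with a negative fold, the sign of tnpo3. Median log2 fold changes in the authors' deposited table were 0.809 and -0.995, and the median level did not differ detectably between the signs (difference 0.08 on the log2 scale, permutation test, p = 0.82). Among the 418 genes with a symbol, 166 had a positive and 252 a negative fold.

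Listed genes of the exocrine pancreas and gut had negative folds. The list of digestive tract, liver and pancreas genes had 10 members in the authors' deposited table, all with a negative fold, with a median log2 fold change of -2.03 (Fisher's exact test against the other listed genes, p = 0.00731, adjusted p = 0.0305 over 8 lists). Carboxypeptidase genes cpa1 and cpb1 stood at -2.08 (standard error 0.16) and -1.96 (0.19) in the authors' deposited table, elastase gene ela2 at -3.37 (0.31) and amylase gene amy2a at -2.26 (0.23), with adjusted p of 6.65e-34, 1.34e-22, 5.89e-25 and 1.61e-19. Among genes with a proper symbol, others of the largest negative folds in the authors' deposited table were the cytochrome P450 genes cyp3c4 (-3.43) and cyp2n13 (-2.57), the glycolysis regulator gene PFKFB1 (-3.29), and PTGR1 (-2.85). Next among such genes in the authors' deposited table came elastase genes CELA1 (-2.55) and ela3l (-2.33), RNF180 (-2.35) and the phosphatase gene alp3 (-2.22).

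Listed cell cycle genes had mostly positive folds. Of the cell cycle and DNA replication list, 7 members had a positive fold and 1 a negative fold in the authors' deposited table (Fisher's exact test, p = 0.00763, adjusted p = 0.0305), with a median log2 fold change of 0.82. The mitotic kinesin genes kif11 (1.14, standard error 0.19) and cenpe (0.91, 0.23), the anaphase activator gene cdc20 (0.74, 0.18) and the spindle gene tpx2 (0.88, 0.24) were positive in the authors' deposited table, while cyclin D1, ccnd1, was negative (-0.33, 0.10). The excess of positive over negative cell cycle genes was 3 at an adjusted p of 0.01 and 1 at a log2 fold of 1, and neither passed. Among genes with a proper symbol, the largest positive folds in the authors' deposited table were those of the tetraspanin gene tspan5b (3.51), the meiotic recombination gene msh4 (3.41), the ciliary dynein gene dnai1 (2.99), and ccbl2 (2.65). Next among such genes in the authors' deposited table came the RNA-binding protein gene RBM33 (2.304), the cyclin-dependent kinase inhibitor gene cdkn1ba (2.26), CCBL2 (2.17), ptk2ba (2.03), STPG2 (1.93) and MSH5, the partner of msh4 in meiosis (1.81).

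In the authors' deposited table the SR genes srsf1b (log2 fold change 1.22, adjusted p = 1.98e-13) and srsf7a (0.47, adjusted p = 0.00586) were positive. The hnRNP genes hnrnpua (-0.67), hnrnpd (-0.62), ptbp1a (-0.36) and matr3l1.1 (-0.36) were all negative in the authors' deposited table. Neither split passed the adjustment over lists (Fisher's exact test, adjusted p = 0.251 for each). The photoreceptor genes gnat1 (-1.40), pde6a (-0.96), sagb (-0.97) and grk1b (-0.70) were negative in the authors' deposited table, without passing the adjustment (adjusted p = 0.251). Of the transport receptors, ipo8 (1.17) and tnpo1 (-0.37) were listed in the authors' deposited table, with log2 folds of both signs. The nervous system genes syn2a (0.36), mpz (0.78) and plp1b (0.90) were positive and mbpa (-0.44) negative in the authors' deposited table (adjusted p = 0.408). The muscle gene pvalb4 stood at -0.63, and no member of the lists for core spliceosome, cartilage, erythroid, interferon, lymphoid, myeloid, p53, ribosome biogenesis or stress genes was in the authors' deposited table. Zebrafish wild-type libraries were 2 of mixed background A and 1 of B, and all 3 mutant libraries were of background B, so genotype and background were only partly separate in every zebrafish comparison.

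**Figure D3:**
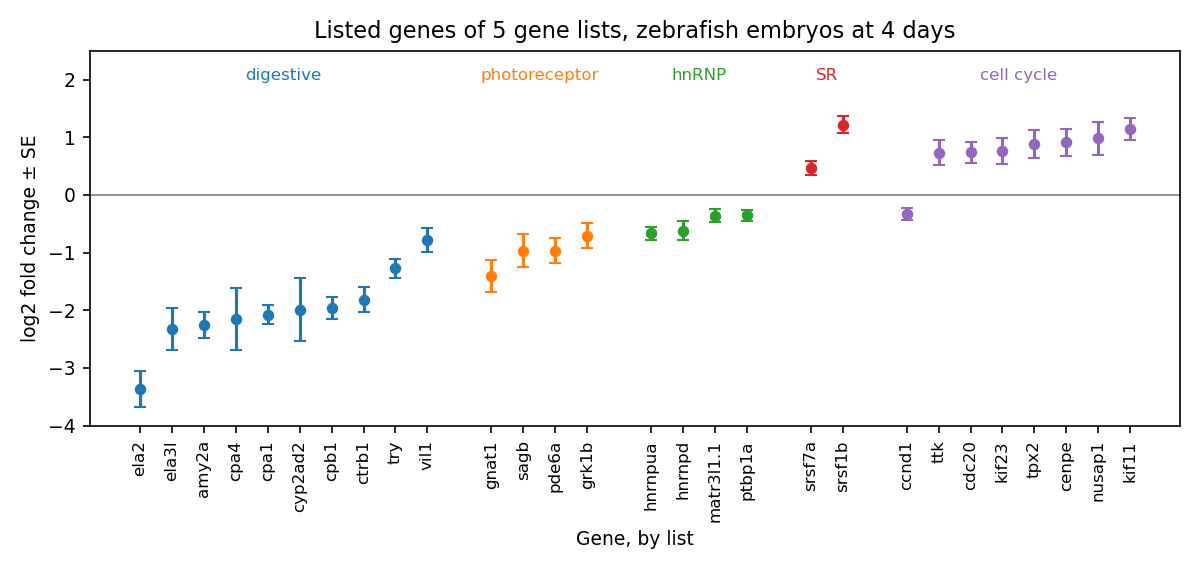
log2 fold change ± standard error in the authors' deposited table for members of 5 gene lists in zebrafish embryos, ordered by fold within each list. The 10 digestive genes lie below 0, with a median of -2.03, and 7 of the 8 cell cycle genes lie above it.

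Exon skipping changed mostly one way. In mouse, 1110 events at 1057 exons in 850 genes changed, 1050 with lower inclusion in group 2 and 60 with higher inclusion. The same exon can belong to more than 1 event. The Tnpo3 exon, which may be deleted from the DNA, is among the 1110. Counting 1 event per gene, 799 of 850 genes (94.0%, 95% interval 92.2% to 95.5%) were lower (exact binomial test, p = 9.98e-174). In zebrafish 836 events at 820 exons in 710 genes changed, 734 lower and 102 higher, and 629 of 710 genes (88.6%, 86.0% to 90.8%) were lower (exact binomial test, p = 5.71e-106). The median change was -0.158 for lower and 0.148 for higher events in mouse, and -0.168 and 0.151 in zebrafish. Of the lower events, 587 in mouse (55.9%) and 536 in zebrafish (73.0%) had a group 1 inclusion of at least 0.9, while the median over all tested events was 0.982 and 0.992. The 3 libraries of one group lay apart from the 3 of the other in 94.1% of changed mouse events and 90% of zebrafish events, which were called for a difference between these libraries. Over all tested events the shares were 24.2% and 27.4%, where chance alone gives 10%. The quasi-binomial model called 815 mouse and 646 zebrafish events, sharing 790 and 607 with the rMATS calls. Both kinds of call used the same difference in inclusion, so their directions could not differ. Limma on logit inclusion called 62 mouse events with a pseudocount of 0.5 reads and 413 with 2 reads, and 539 and 615 zebrafish events.

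**Figure D4:**
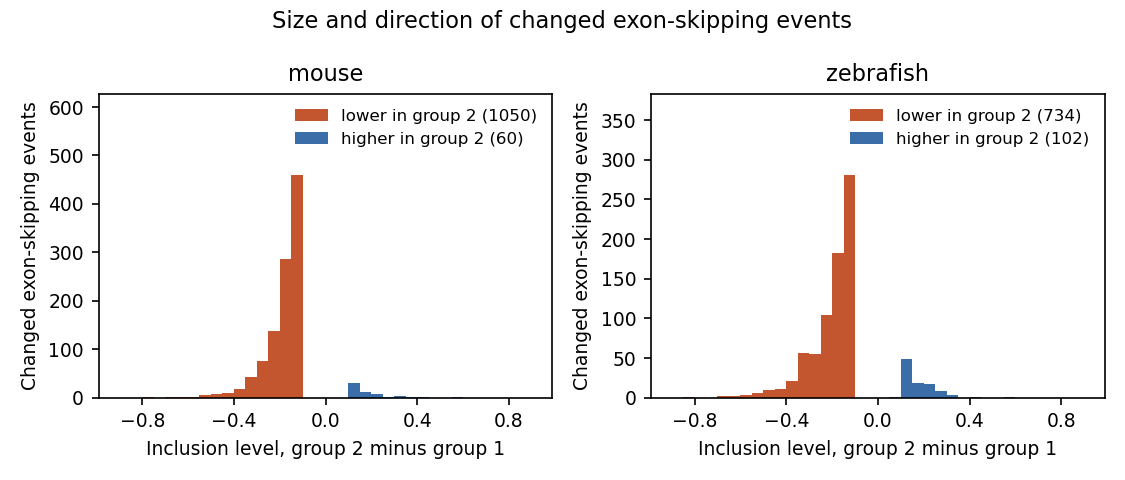
Number of changed exon-skipping events by the difference in inclusion level, group 2 minus group 1, for mouse and zebrafish, in steps of 0.05. Lower events number 1050 and 734, and higher ones 60 and 102.

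The largest losses of inclusion in mouse were at Tmem241 (0.966 ± 0.059 in group 1 and 0.216 ± 0.092 in group 2, SD, n = 3), Btbd8 (0.918 ± 0.143 and 0.244 ± 0.162), the COPII coat gene Sec31b (0.882 ± 0.204 and 0.292 ± 0.088), and Rell2 (0.956 ± 0.077 and 0.385 ± 0.152). Others were the methyltransferase gene Hemk1 (0.876 ± 0.139 and 0.330 ± 0.099), the clathrin adaptor gene Ap1m1 (0.790 ± 0.196 and 0.258 ± 0.067), Cd6, Zfr2 (0.895 ± 0.182 and 0.390 ± 0.074) and C030017K20Rik (0.866 ± 0.131 and 0.362 ± 0.089), beside Tnpo3. The Tnpo3 loss may come from the floxed allele and not from splicing. The largest gains were at the inositol kinase gene Ppip5k2 (0.312 ± 0.040 and 0.909 ± 0.157), the transcription factor gene Mef2d (0.419 ± 0.097 and 0.847 ± 0.066), Rprd2 (0.429 ± 0.072 and 0.804 ± 0.044) and the adhesion receptor gene Cd97 (0.0843 ± 0.0081 and 0.452 ± 0.058). Gm26782 (0.0465 ± 0.0218 and 0.380 ± 0.108), Spef2 (0.472 ± 0.121 and 0.800 ± 0.103) and Zfp945 (0.254 ± 0.088 and 0.509 ± 0.055) were also higher in group 2. So were Pisd-ps1 (0.307 ± 0.051 and 0.557 ± 0.111), the MYC partner gene Max (0.408 ± 0.028 and 0.654 ± 0.018) and the translation factor gene Eif4a2 (0.497 ± 0.030 and 0.739 ± 0.004). Tmem241, Btbd8, Sec31b, Ppip5k2 and Zfr2 had a mean of only 14.2, 13.3, 12.2, 15.0 and 16.8 reads per library, and the quasi-binomial model did not call Ppip5k2 (adjusted p = 0.0612) or Zfr2 (adjusted p = 0.0807). The Eif4a2 exon, at chromosome 16, 23112351 to 23112457, rested on 2729.3 reads per library (adjusted p = 2.04e-20). Before division by form length, Rell2 had 79 inclusion reads and 1 skipping read in group 1, and 40 and 15 in group 2. Hemk1 had 216 and 7 in group 1, and 95 and 38 in group 2.

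In zebrafish the largest losses were at the synapsin gene SYN2 (0.938 ± 0.108 in group 1 and 0.111 ± 0.192 in group 2, SD, n = 3), si:ch211-198m17.1 (1.0 and 0.336 ± 0.022), the metalloprotease gene adamts13 (0.995 ± 0.009 and 0.338 ± 0.161) and the spectrin gene SPTBN5 (1.0 and 0.364 ± 0.116). Others were si:ch211-262n1.5 (0.869 ± 0.122 and 0.253 ± 0.053), SNAPC2 (0.981 ± 0.032 and 0.403 ± 0.193) and her8.2 (0.889 ± 0.192 and 0.332 ± 0.349). Next came the calcium channel gene CACNA1F (0.899 ± 0.088 and 0.345 ± 0.207), the acetyltransferase gene KAT7 (0.949 ± 0.048 and 0.411 ± 0.065) and si:ch211-40k21.5 (0.810 ± 0.143 and 0.280 ± 0.220). The gains were led by apol1 (0.196 ± 0.339 and 0.793 ± 0.186), cherp, a splicing-associated gene (0.408 ± 0.098 and 0.843 ± 0.016), EHBP1L1 and FEZ2. Others were the calcium sensor gene stim1b (0.425 ± 0.062 and 0.727 ± 0.190), yy1b, CARKD, the RNA-binding protein gene rbm4.1 (0.560 ± 0.033 and 0.853 ± 0.022), the myelin gene mag (0.369 ± 0.129 and 0.649 ± 0.073) and zgc:66474 (0.633 ± 0.117 and 0.900 ± 0.089). The quasi-binomial model did not call apol1 (adjusted p = 0.188), EHBP1L1 (0.124), FEZ2 (0.0874), yy1b (0.0901) or CARKD (0.0688).

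Genes that themselves regulate splicing were among those whose exons changed. In mouse, 16 of 40 tested hnRNP and other splicing regulator genes had a changed exon (40.0%, against 11.6% of other genes; odds ratio 5.10, 95% interval 2.70 to 9.64; Fisher's exact test, p = 4.49e-06, adjusted p = 7.63e-05 over 17 lists), and 17 did when adjusted over the list alone. Of their events 14 were lower in group 2 and 4 higher. Exon 5 of Hnrnph1 went from 0.440 ± 0.050 to 0.229 ± 0.019 and exon 6 of Hnrnpdl from 0.961 ± 0.010 to 0.823 ± 0.010 (SD, n = 3). Exon 9 of Ewsr1 went from 0.932 ± 0.059 to 0.639 ± 0.016 and exon 8 of Hnrnpa2b1 from 0.257 ± 0.059 to 0.120 ± 0.014 (SD, n = 3). The 4 higher events, chosen for naming after their values were seen, were in Hnrnpl (0.104 ± 0.022 to 0.204 ± 0.040), Hnrnpll (0.331 ± 0.038 to 0.444 ± 0.041), Ptbp3 (0.1996 ± 0.013 to 0.310 ± 0.016) and Hnrnpd (0.549 ± 0.067 to 0.685 ± 0.050). In zebrafish 5 of 33 genes of this list changed (15.2% against 10.7%, adjusted p = 1; 8 genes when adjusted over the list alone), among them syncripl (0.852 ± 0.015 to 0.688 ± 0.034), mbnl2 (0.514 ± 0.046 to 0.327 ± 0.047), ptbp1a (0.866 ± 0.051 to 0.717 ± 0.076) and ptbp2b. The ratio of the odds ratios of mouse and zebrafish was 3.42, a difference that did not pass the adjustment over 5 tests.

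In genes for SR proteins, the cargo of Tnpo3, some changed exons in mouse lay in no protein-coding transcript. They were annotated in transcripts subject to nonsense-mediated decay, as so-called poison exons are. Mouse Srsf6 (chromosome 2, 162932815 to 162933082) went from 0.291 ± 0.028 to 0.116 ± 0.024 and Srsf3 (chromosome 17, 29039454 to 29039909) from 0.326 ± 0.028 to 0.213 ± 0.014, and zebrafish srsf6b from 0.367 ± 0.072 to 0.130 ± 0.029 and srsf3a from 0.181 ± 0.024 to 0.0316 ± 0.0074 (SD, n = 3; adjusted p of 2.31e-32, 3.07e-14, 2.89e-05 and 1.57e-17); the annotation was read for mouse only. Other SR list members with lower inclusion were the kinase gene Clk1 and Srrm2 in mouse (0.910 ± 0.038 to 0.804 ± 0.030, and 0.891 ± 0.042 to 0.766 ± 0.009) and scaf4a and srsf11 in zebrafish (0.995 ± 0.009 to 0.844 ± 0.037, and 0.205 ± 0.031 to 0.0908 ± 0.0258). In zebrafish 8 of 25 tested genes of the SR list changed (32.0% against 10.6%, odds ratio 3.95, 95% interval 1.70 to 9.19; Fisher's exact test, p = 0.00344), which failed the adjustment over 17 lists (adjusted p = 0.0585); 10 changed when adjusted over the list alone. With events called by the quasi-binomial model the zebrafish odds ratio was 5.21 and passed (adjusted p = 0.0118), and it ranged from 6.28 to 10.01 with a library left out. In mouse 7 of 35 changed (20% against 11.7%, adjusted p = 0.605; 9 when adjusted over the list alone).

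**Figure D5:**
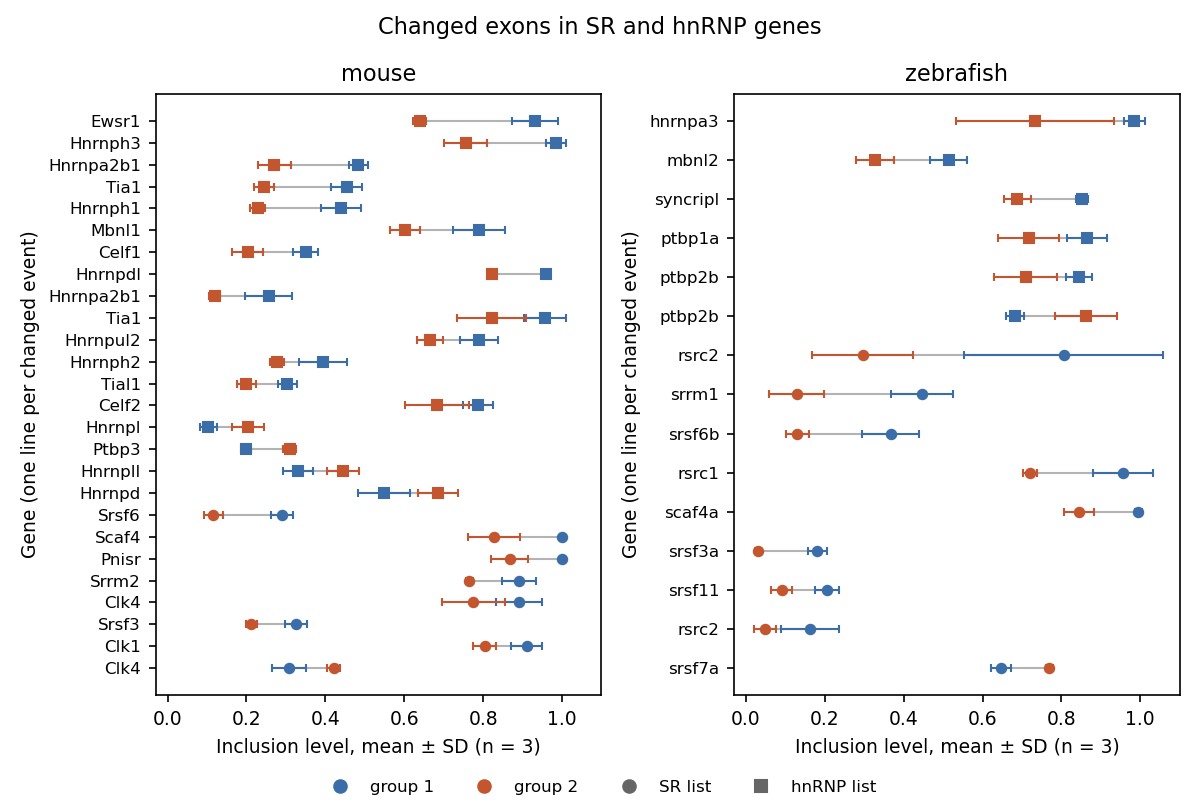
Inclusion level (mean ± SD of 3 libraries) of every changed event in SR genes (circles) and hnRNP and related genes (squares), in group 1 and group 2, 1 line per event. In mouse 14 of the 18 squares moved to lower inclusion in group 2, and in zebrafish 8 of the 9 circles did.

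Of 43 tested genes of T-cell identity and TCR signalling, 5 had a changed exon, a share of 11.6% against 11.7% of other genes (adjusted p = 1), and all 6 of their events were lower in group 2. The odds ratio of 0.992 was 1.73 with quasi-binomial calls and 1.57 to 2.88 with a library left out, never passing the adjustment. Exon 4 of Cd6, which encodes a T-cell surface receptor, went from 0.779 ± 0.195 to 0.273 ± 0.058 (adjusted p = 7.62e-08). Exon 4 of the zinc finger gene Ikzf1 went from 0.707 ± 0.030 to 0.546 ± 0.011 (3.61e-24) and exon 5 of Tcf7, the TCF1 transcription factor gene, from 0.569 ± 0.030 to 0.419 ± 0.020 (1.12e-17). A 147 bp coding exon of Ptprc, which encodes CD45, went from 0.951 ± 0.016 to 0.850 ± 0.051 (4.62e-04). Interferon response genes changed in 9 of 32 cases (28.1% against 11.6%, odds ratio 2.97, 95% interval 1.37 to 6.44; Fisher's exact test, p = 0.0092, adjusted p = 0.0782), short of the threshold, with all 10 events lower. Examples were Zbp1 (1.0 to 0.787 ± 0.052), Psmb9 (0.971 ± 0.015 to 0.862 ± 0.017), Samhd1 (0.418 ± 0.033 to 0.242 ± 0.027) and Xaf1 (0.788 ± 0.016 to 0.656 ± 0.051). Core spliceosome genes changed in 2 of 57 cases, Prpf39 and Prpf3 (odds ratio 0.272, Fisher's exact test, p = 0.0597, adjusted p = 0.338).

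Further mouse lists had 4 genes of thymocyte maturation (H2-Q7, Itgb7, Ly6c1 and Ms4a4c, of 29) and 3 exportin genes (Xpo4, Xpo6 and Xpo7, of 27 transport receptors). There were 2 activation or regulatory genes (Ctla4 and Ikzf2, of 15), 2 cell cycle genes (Cenpa and Kif23, of 31) and 1 each of p53 targets (Ddb2), ribosome biogenesis (Gnl3) and stroma (Pecam1). None passed the adjustment, and the lists of B cells, double-positive thymocytes, erythroid, myeloid and stress genes had none. In zebrafish, changed genes included col6a3, matn4, acana and col11a2 of the cartilage and matrix list (4 of 22). They also included the nervous system genes elavl3 (0.651 ± 0.056 to 0.868 ± 0.010), gad1b (0.699 ± 0.043 to 0.864 ± 0.027) and plp1b (0.299 ± 0.053 to 0.0962 ± 0.0255). Others were the cell cycle genes nusap1, e2f4 and cdt1, the p53 targets gtse1 and mdm2, the lens genes crygmxl2 and lim2.5, and 1 each in digestive (cpa1), muscle (neb) and stress (atf5b) genes. Each of these lists had an adjusted p of 1 (Fisher's exact test), and transport receptors, core spliceosome, ribosome biogenesis, erythroid, interferon, lymphoid and myeloid lists had no changed gene among those tested.

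Expression and splicing changes met in the same genes more often than by chance. In mouse, 24 of 91 genes of the authors' deposited table with a tested event also had a changed exon, where 10.7 were expected (odds ratio 2.75, 95% interval 1.72 to 4.41; Fisher's exact test, p = 9.7e-05). In zebrafish 38 of 251 did, with 26.9 expected (odds ratio 1.51, 1.06 to 2.16, Fisher's exact test, p = 0.0282). The 24 mouse genes include Tnpo3 itself, whose exon may be deleted from the DNA. The mouse genes with the lowest FDR included Mogs, a glucosidase of protein glycosylation (0.910 ± 0.031 to 0.701 ± 0.040), and Uba7, the ISG15-activating enzyme gene (0.727 ± 0.055 to 0.408 ± 0.110). Others were Olfr56 (0.941 ± 0.052 to 0.554 ± 0.078) and Prpsap1 (0.956 ± 0.014 to 0.813 ± 0.049). Before division by form length, Uba7 had 2873 inclusion and 52 skipping reads in group 1, and 1647 and 119 in group 2. The zebrafish genes included the creatine kinase gene ckba (1.0 to 0.710 ± 0.054), the nucleoside transporter gene SLC28A2 (0.990 ± 0.011 to 0.705 ± 0.127), nusap1 (0.978 ± 0.021 to 0.753 ± 0.037) and acsbg1 (0.862 ± 0.124 to 0.348 ± 0.078). With quasi-binomial calls, the mouse overlap fell short of the threshold without the second value of group 2 (odds ratio 1.76, Fisher's exact test, p = 0.148) and without the third value (1.62, p = 0.189).

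The series asks about conservation between the species. Among 2160 genes tested in both, 278 mouse and 218 zebrafish genes had a changed exon and 43 had one in both, where 28.1 were expected (odds ratio 1.79, 95% interval 1.25 to 2.56; Fisher's exact test, p = 0.00264). In 35 of them inclusion was lower in group 2 in both species, in 1, the mitochondrial fission gene Mff, it was higher in both, and in 7 the directions differed. Within each species alone, 94.0% and 88.6% of genes were lower, and shared direction was not tested against these shares. Genes lower in both included Bin1 (mouse 0.840 ± 0.096 to 0.545 ± 0.045), Sec31a, Med25, Kat7, Huwe1, Eps15 and Rev3l. Lengths were compared for 1 changed exon per gene and species, the one with the largest difference. In no gene did these exons have the same length in both species. Other changed exons were not compared, and exons were not matched between species in any other way. Once read depth and number of events were modelled, the overlap was not detectable (logistic model, odds ratio 1.29, 95% interval 0.867 to 1.92). In level, 7 genes were listed in both species: tnpo3, acsbg1 and galm had negative log2 folds in both species in the authors' deposited table, cdh15 positive folds in both, and chdh, pdzk1 and vil1 opposite signs.

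Exons with lower inclusion were longer than unchanged exons, and exons with higher inclusion shorter. In mouse, 1 exon per gene, the median length was 152.5 bp for lower exons (806 genes) and 69 bp for higher exons (58 genes), against 116 bp for unchanged exons (permutation test, p = 1e-05, the smallest it could give, and p = 2e-05). In zebrafish the medians were 150 bp (634 genes) and 60 bp (87 genes) against 115 bp (permutation test, p = 1e-05 each, the smallest it could give). Lengths divisible by 3, which keep the reading frame, made up 81.6% of higher zebrafish exons against 50% of unchanged ones (Fisher's exact test, p = 1.72e-09, adjusted p = 1.4e-08), and 39.8% of lower mouse exons against 34.9% (p = 0.007, adjusted p = 0.019). Against unchanged exons matched on inclusion and coverage, the higher exons were no longer detectably shorter (mouse -22 bp, permutation p = 0.11; zebrafish -18 bp, p = 0.058), and the differences in divisibility by 3 were not detectable (zebrafish higher 5.75 points, Fisher's exact test, p = 0.459; mouse lower 1.61 points, p = 0.54). Lengths of the flanking introns did not pass the adjustment (adjusted p of at least 0.054). Downstream introns of lower mouse exons differed by 43 bp from those of unchanged exons, but by -453 bp from matched ones (permutation p = 5e-04), and those of higher exons by 1845 bp with quasi-binomial calls (permutation p = 0.0043).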

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

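The share of low-level mouse genes with a positive fold and the 2 tests of single zebrafish libraries in changed exons and among the cases of listed genes were chosen after the result was seen.

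The species differed in how one-sided the exon changes were, which is why this result was taken up again. Genes with a changed exon were lower in group 2 in 94.0% of mouse and 88.6% of zebrafish cases, an odds ratio of 2.02 (95% interval 1.4 to 2.91; Fisher's exact test, p = 1.64e-04, adjusted p = 8.2e-04 over 5 tests), and the difference held with quasi-binomial calls (p = 0.00467). The species lay closer by limma calls, counted by event and without a test. Lower events made up 96.77% in mouse and 95.18% in zebrafish with 0.5 reads added, and 95.64% and 93.98% with 2 reads. Exons near full inclusion have room only to fall, but among changed exons with a mean inclusion of 0.3 to 0.7 the share of genes lower in group 2 was still 87.6% (82.7% to 91.5%) in mouse and 80.0% (72.4% to 86.3%) in zebrafish, which argues against room to fall as the only source of the direction. Splits of the 6 libraries were too few to judge the number of calls: of 10 splits only 1, the real one, gave 815 mouse events, and the highest other gave 4, and only 1 of 10 gave 646 zebrafish events, with 4 as the highest other. Cell type, species, read depth and annotation differ between the 2 data sets, and their parts were not tested.

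Of the listed mouse genes below 1 log2 CPM, 96.2% (89.2% to 99.2%) were positive in the authors' deposited table, which argues against noise that makes large folds of either sign. An expressed gene on the same strand ended within 10 kb upstream of 43 of 141 positive genes (30.5%). The share was 5.88% among unlisted protein-coding genes with a mean below 1 junction read per library (odds ratio 7.02, 4.87 to 10.1, Fisher's exact test, p = 2.93e-19). Below 1 log2 CPM, 20 of 74 positive genes had such a neighbour (5.93, 3.53 to 9.95), such as Cpne9, 915 bp after Mtmr14, and Serpinf2, 1353 bp after Wdr81. Listed genes were of any type and many were expressed, so ratios against this background are not like for like. On the opposite strand the ratio was 1.21 (0.564 to 2.60), which argues against an active neighbourhood whatever the strand as the source of the positive folds. A same-strand gene downstream had a ratio of 2.46 (1.47 to 4.1) for positive genes and an overlapping one 5.51 (0.743 below 1 log2 CPM), and negative genes had 2.23 and 3.87 for an upstream gene on the same and the opposite strand, though positive genes had a same-strand one more often than negative genes (odds ratio 3.14, 1.56 to 6.35). Reads running on from the upstream gene could therefore make up part of the positive folds, and a same-strand neighbourhood stays open.

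Zebrafish groups differed in background as well as genotype, since only 1 wild-type library shared the background of the mutants. No library lay closer to the other group in more than 14.2% (11.9% to 16.8%) of changed exons or 19.9% (16.2% to 24.0%) of listed genes, but these items were called for a difference between the same groups, which keeps such shares low, so the test decides nothing. Among the cases in group 1, the second value in the cells held 54 of 113 in exons (47.8%; exact binomial test against equal shares, p = 0.00183) and 22.0% (16.2% to 28.7%) among listed genes, where the third value led. The cells carry no replicate numbers, so no value was tied to the background B library. Background and genotype cannot be told apart as sources of the zebrafish changes, since the design joins them in 5 of 6 libraries.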

How the results depend on the processing

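The overlaps, the expression lists and the model with spread from every group were tested under alternatives chosen after the results were seen; the rest were planned. Replicate numbers here give the order of the values in a cell, not the numbers in the labels. Of 40 named exons, 33 were kept by the quasi-binomial model and 18 in every omission of a library. With a library left out, 0 changed direction. The exons were named for the largest differences in these same libraries, which made a change of direction unlikely. The quasi-binomial and limma settings took direction from the same difference in inclusion, so they could not change it. Where a result below moved, the cause was not tested, except that thresholds on size or p keep fewer or more items by construction. Changed events numbered 2103 and 319 in mouse and 1423 and 304 in zebrafish at differences of 0.05 and 0.2; limma gave 62 and 413 in mouse and 539 in zebrafish with 0.5 reads added. The quasi-binomial model called 470 to 683 mouse events with 1 library left out, 470 without group 2 replicate 2, and 446 to 529 zebrafish events. With spread from every group it called 592 to 958 in mouse, 592 and 655 without group 2 replicates 2 and 3, and 13 to 747 in zebrafish, with 60, 13 and 254 without group 2 replicates 1, 2 and 3. Listed genes fell to 155 in mouse and 333 in zebrafish at a log2 fold of 1, and to 455 in zebrafish at an adjusted p of 0.01. The T-cell list had odds ratios of 1.73 by the quasi-binomial model and 1.57 to 2.88 with a library left out, on the other side of 1 from 0.992, none passing (lowest adjusted p = 0.154, Fisher's exact test). Interferon genes passed without group 1 replicate 2 (4.328), in a range of 2.101 to 4.328 with a library left out. Zebrafish SR genes passed at 5.21 in the quasi-binomial model and at 6.277 to 10.01 with a library left out. The logistic model gave odds ratios of 3.13 for interferon genes and 3.76 for zebrafish SR genes. Lists without a changed gene had no logistic fit, so an adjustment there covers fewer than 17 lists and is not counted as a pass. The mouse overlap of expression and splicing was 1.619 to 2.591 with a library left out, and fell short of the threshold without group 2 replicates 2 (1.755) and 3 (1.619); that between species was 1.29 in the logistic model, 1.412 in the quasi-binomial model, and below 1 without mouse group 2 replicate 2 (0.992) and zebrafish group 1 replicate 2 (0.9962). Other omissions gave 1.487, 1.405, 1.163, 1.087 and 1.049 for mouse libraries and 1.135, 1.016, 1.197, 1.504 and 1.135 for zebrafish libraries. Against matched exons, divisibility by 3 differed by 1.61 points for lower and -8.62 for higher mouse exons, and -1.74 and 5.75 in zebrafish (-0.221 for lower by the quasi-binomial model); length differed by -22 and -18 bp for higher exons; downstream introns by -453 and -260 bp for lower and higher mouse exons, and 1845 bp for higher ones by the quasi-binomial model. Positive minus negative genes at a log2 fold of 1 were 1 for cell cycle (3 at an adjusted p of 0.01), -9 for digestive, 0 for hnRNP and 0 for nervous system genes. No paired analysis was possible because the values in a cell carry no replicate numbers. Rerunning edgeR or DESeq2, a replicate block and expression without single libraries were not run. In data simulated at the real depths, the quasi-binomial model recovered 19% and 20% of changes of 1 on the log2 odds scale and 76% and 70% of changes of 2, in mouse and zebrafish. Those changed events lay away from full inclusion, unlike many of the real ones.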

Other observations

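The examples of mitosis genes, the places of exons and the comparisons of AGG, GAG and of higher exons were chosen after the values were seen.

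Further zebrafish genes of mitosis had positive log2 fold changes in the authors' deposited table, chosen by name after the values were seen: the kinesin genes KIF14 (1.54, standard error 0.40) and kif2c (0.80, 0.19), the spindle gene hmmr (1.404, 0.23), the cohesin protector gene SGOL1 (1.26, 0.20), the cytokinesis genes prc1a (1.05, 0.26), anln (0.9004, 0.19) and ect2 (0.89, 0.20), the checkpoint gene bub1bb (0.96, 0.23) and INCENP, of the chromosomal passenger complex (0.89, 0.19). The inhibitor gene cdkn1ba rose as well (2.26, 0.16) in the authors' deposited table. No test was made of these genes as a set.

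In mouse, exons lower in group 2 were coding in 84.9% of cases and annotated only in transcripts subject to nonsense-mediated decay in 5.56%, against 87.2% and 4.27% of unchanged exons; exons higher in group 2 were coding in 62.7%, in untranslated regions only in 15.3%, in decay transcripts in 10.2% and noncoding in 11.9%, without a test. Decay exons of the hnRNP genes Hnrnpl and Hnrnpll were higher in group 2, while those of Srsf3 and Srsf6 were lower.

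A hypothesis was that exons lower in group 2 hold more GGA, a purine-rich motif bound by SR proteins such as SRSF1. In 792 lower mouse exons GGA stood at 2.86 ± 1.45 (SD) per 100 bases against 2.39 ± 1.36 in 792 unchanged exons of matched length, a difference of 0.466 (0.326 to 0.601; permutation p = 2e-05, the smallest it could give). TCC, its reverse complement, differed by 0.141 (0.0323 to 0.259; permutation p = 0.019), so GC content, which TCC shares, did not alone give the GGA difference. Percent GC itself was higher by 1.67 points (0.942 to 2.44) in lower exons and differed by -3.91 points (-7.57 to -0.183) in higher ones, and purine content by strand was not tested. AGG differed by 0.337 (permutation p = 2e-05) and GAG by 0.0983 (p = 0.26), and 51 higher exons held less GGA than matched ones (-0.591, -1.14 to -0.0343; permutation p = 0.033). The GGA difference of 0.466 may reflect exons that depend on SR proteins, which was not tested directly. The unchanged exons were matched on length only, so differences in inclusion level or coverage could also contribute.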
